A study of Rattus norvegicus with 12 samples.

How the data were processed

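Total RNA was taken with TRIzol from rat nucleus pulposus cells and made into strand-marked libraries, per the labels, in 4 groups of 3 libraries: NPPC-Exo, miR-Exo, and each of these with erastin. The labels do not say whether the 3 libraries of a group came from separate cultures or animals, so the p values measure the spread between libraries and no more than that. The authors deposited raw counts per gene for the 12 libraries, and beside them FPKM, which the deposited table gives per kilobase of gene and by library size, rounded to 2 decimals. Per the labels the reads were processed with StringTie on the mRatBN7.2 build, with no version given, and the aligner, the counting tool and any filter are not given in the sources used here. The coordinates in the table reach 282702424 on chromosome 1 and some gene names belong to an older assembly, so the build is uncertain and no coordinates are printed. Of the counts from 1 to 20, 57.2% were even, as when both mates of a read pair are counted, and a setting with halved counts was run for this reason. Genes keep the symbols of the deposited table, and 15844 of the 21071 genes had an Entrez ID found in the reference table of gene names. Gene families with many copies, such as small nuclear RNAs, share reads and are not discussed.

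Library totals ran from 54616827 to 68865720 counts. Genes with too few counts were left out by the filterByExpr function of edgeR, which kept 15650. Counts were scaled by trimmed means of M values (TMM), with factors from 0.877 for an NPPC-Exo library to 1.15 with erastin and miR-Exo, and fitted with quasi-likelihood negative binomial models on the 4 group means, all 12 libraries sharing the estimate of spread. R 4.3.3 was used with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The comparisons were erastin against none for each kind of exosome, miR-Exo against NPPC-Exo without and with erastin, and the interaction. A gene is said to change, rise or fall where its p, adjusted by Benjamini and Hochberg over the genes of that comparison, was under 0.05. CPM were divided by the scaled library totals, and a fold change from a group with 0 counts is given as a bound from 3 counts.

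Before the data were examined, 34 gene lists, the comparisons, the test and the alternatives were written down, with the quasi-likelihood test on counts as the choice if the table held counts. A list was tested with camera at a preset correlation between genes of 0.01, in both directions, where at least 5 members were tested, which left out the erythroid and adipocyte lists, and p were adjusted over the 32 lists of a comparison. The adjusted p of the same test with the correlation estimated from the data follows that of each list called, after the word estimated. The fry test, planned as an addition, asks whether a list moved without setting it against the other genes. Its unadjusted p is given for the ferroptosis and miR-221 lists, and for other lists only where set beside the latter. A list's median is also given with genes at 0 counts in a group at their bound where that changed it by more than 0.1. The genes named were chosen by rule: per comparison the 10 with the largest change each way (5 for the interaction) among genes with a proper symbol and a mean FPKM of at least 2 in the highest group. Except for the interaction, the groups of these genes also did not overlap. To these came up to 4 members of each list with the smallest adjusted p, and 13 genes of ferroptosis, iron, cell cycle and matrix whatever their result. Not all genes that met the rule are named, and a gene outside it is said to be so.

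In a test on simulated data, counts were drawn gene by gene from the mean level over all libraries and the fitted spread. With 200 changed genes placed among those above 1 CPM, 55.2% of genes with a true 1.5-fold change were recovered for the kinds of exosome without erastin. For 2-fold and 4-fold changes 83.6% and 98.5% were recovered there. The shares were 49.3%, 80.6% and 95.5% for erastin under NPPC-Exo, and 41.8%, 71.6% and 97% for the interaction, where 8.5% of the calls were unchanged genes. The simulated libraries shared no component of spread within groups and had fewer changed genes than the data, so these shares may not carry over. The alternatives run were other scaling, filters and pseudocounts, DESeq2, limma on FPKM, a replicate block, only the groups compared, and leaving out each library. Limma-trend with a pseudocount of 1 had been the planned main test for a table without counts. It was made an alternative after the data were seen. Library size alone, halved counts, a minimum of 5 CPM, and removal of the main component of the spread within groups were also chosen then. That component is the leading singular vector of the deviations of log2 CPM from the group means over 10162 genes, and its slope in each group was taken out of the group means. The planned test of miR-221-3p seed sites was not run, since no genome or 3′ UTR sequence was held, and GC content was not analysed here for the same reason.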

Results

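RNA of rat nucleus pulposus cells, the cells of the gel-like core of the intervertebral disc, was sequenced in 12 libraries that fall into 4 groups of 3. The cells received exosomes, small vesicles shed by cells, from nucleus pulposus progenitor cells (NPPC-Exo) or from such progenitors overexpressing the microRNA miR-221-3p (miR-Exo), each at 50 µg/mL. Each kind of exosome was given without erastin and with erastin, a compound that blocks cystine import and starts ferroptosis, an iron-dependent death by lipid peroxidation. The labels give 0.1 to 5 µM of erastin for 48 h and no dose for a single library. The titles of these libraries name erastin, while the deposited counts and the sample descriptions name them Model in its place. All groups received exosomes, so the effect of the exosomes themselves is not analysed here.

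Total counts were 63895336, 60480706 and 63046912 in the NPPC-Exo libraries and 63076347, 61076654 and 68865720 in the miR-Exo libraries. They were 54616827, 61410653 and 63574700 with erastin and NPPC-Exo, and 59027181, 59322219 and 56418635 with erastin and miR-Exo. A gene with 0 counts in a library could still have had up to 0.0440 to 0.0565 CPM (counts scaled to a common library size), from 3 counts, and this limit covers counting error only. The table lists 21071 genes, of which 15650 had enough counts to be tested. Principal component 1 held 48.8% of the variance and separated the erastin libraries from the others, and component 2 held 12.5% and separated the kinds of exosome. Log2 fold changes are given ± SE of the fit, and CPM as mean ± SD with n = 3 in every group. For a gene list, the value after the adjusted p and the word estimated is its adjusted p with the correlation between genes estimated from the data.

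The reads at Mir221, the gene of the miR-221 hairpin, tell the kinds of exosome apart. Mir221 stood at 0.310 ± 0.009 CPM with NPPC-Exo and 27.7 ± 1.36 CPM with miR-Exo, and at 0.352 ± 0.051 and 24.2 ± 0.30 CPM in the same order with erastin. The rise had a log2 fold change of 6.47 ± 0.12 without erastin (adjusted p 3.27e-12) and 6.10 ± 0.12 with erastin (adjusted p 4.44e-12). Mir222, which lies 458 bp from Mir221 and is usually transcribed with it, had 10 counts in the miR-Exo libraries against 11 in the NPPC-Exo libraries. The ratio of miR-Exo to NPPC-Exo was 78.1 for Mir221 (95% interval 65.1 to 94.4) and 0.853 for Mir222 (95% interval 0.325 to 2.21). Those intervals cover counting error only and take reads as independent; from the spread between libraries they were 68.8 to 89.9 and 0.529 to 1.45. Libraries of this kind read long RNA, so the level of the mature miRNA was not measured.

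**Figure D1:**
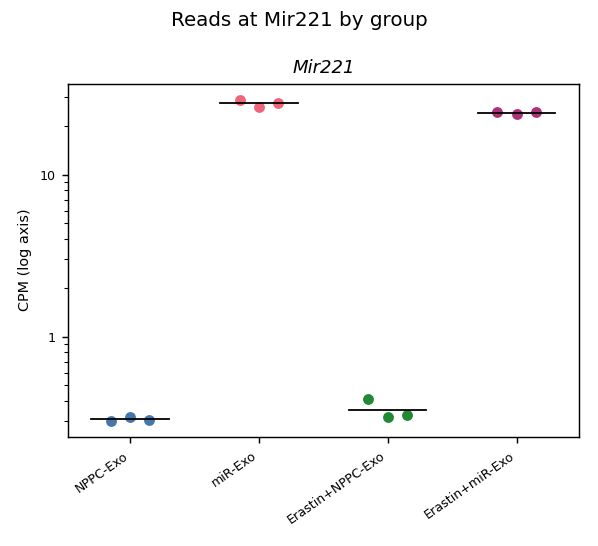
Reads at Mir221 in CPM, on a log axis, for each of the 12 libraries (dots) in the 4 groups; lines are group means. Means were 0.310, 27.7, 0.352 and 24.2 CPM.

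In cells given NPPC-Exo, chemokines that draw monocytes and neutrophils rose steeply with erastin. Ccl2 went from 8.47 ± 0.90 to 1148 ± 190 CPM, a log2 fold change of 7.08 ± 0.20, Ccl7 rose by 6.73 ± 0.21 and Cxcl3 by 6.99 ± 0.43. The growth factors of myeloid cells Csf2 and Csf1 rose by 7.50 ± 0.63 and 2.42 ± 0.07, and Tnfaip3, which NF-κB switches on as its own brake, by 3.50 ± 0.10. Interferon-driven Gbp5, Cxcl10 and Irf1 rose by 4.86 ± 0.15, 4.50 ± 0.16 and 2.50 ± 0.10. Of 32 tested genes of secreted and inflammatory factors 27 were higher and 1 was lower, with a median log2 fold change of 5.0, or 4.6 with genes at 0 counts in a group taken at their bound (adjusted p 1.35e-34, estimated 0.0265). Of 28 interferon-response genes 18 were higher and 0 lower, with a median of 1.55 (adjusted p 6.1e-10, estimated 0.0368).

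Genes of dividing cells were higher under the same treatment: Kif20a and Ccnb1, which act in mitosis, rose by 1.44 ± 0.04 and 1.52 ± 0.06, and Rrm2, which makes DNA precursors, by 1.53 ± 0.06. All 34 proliferation genes were higher, with a median of 1.19 (adjusted p 2.96e-42, estimated 0.00122). Of the apoptosis genes 10 of 20 were higher and 2 lower (median 0.244, adjusted p 0.00161, estimated 0.251), among them Birc3, an inhibitor of caspases that NF-κB induces, at 3.20 ± 0.14, and Apaf1, which activates caspase 9, at 0.76 ± 0.05. Plk2, a kinase of the stress response, rose by 2.16 ± 0.06.

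The matrix of the disc went the other way. Acan, the large proteoglycan that holds water in the disc, fell from 6389 ± 242 to 912 ± 81.5 CPM, a log2 fold change of −2.81 ± 0.07, and Col2a1, its fibrillar collagen, from 1025 ± 314 to 227 ± 26.9 CPM, or −2.18 ± 0.21. Col9a1 and Prelp fell as well, with −1.71 ± 0.06 and −1.92 ± 0.07. The proteases that cut this matrix rose: Mmp3 by 6.50 ± 0.17, Mmp10 by 6.81 ± 0.19, Mmp9 by 5.94 ± 0.21 and Mmp13 by 4.89 ± 0.26, while the inhibitor Timp3 had −2.87 ± 0.13. The list of protease inhibitors was not called (3 higher and 3 lower of 9, median 0.0636, adjusted p 0.493). In the disc matrix list 19 of 31 genes were lower and 4 higher, with a median of −0.895 (adjusted p 2.86e-08, estimated 0.036). The matrix-degrading list as a whole was not called (12 higher and 7 lower of 24, adjusted p 0.0557).

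Fibroblast and contractile genes fell with the matrix. Postn had −2.74 ± 0.05, Col12a1 −2.66 ± 0.06 and Tpm2 −1.78 ± 0.06, and 26 of 32 genes of this list were lower against 2 higher (median −1.02, adjusted p 1.03e-31, estimated 0.00122). Of the mineralisation and hypertrophy genes 12 of 15 were lower and 0 higher (median −1.06, adjusted p 0.00672, estimated 0.153), including Spp1 at −0.81 ± 0.06 and Runx2 at −0.58 ± 0.08. Among the largest falls were those of Mrap2, a partner of melanocortin receptors, at −6.31 ± 0.15, the cell-adhesion gene Esam at −5.44 ± 0.14, the basement-membrane collagen Col4a3 at −4.95 ± 0.10 and the sarcomere gene Myom1 at −4.76 ± 0.22. Endothelial genes were lower as a list (4 lower and 1 higher of 7, median −1.12, adjusted p 0.00061, estimated 0.0596), with Flt1 at −1.71 ± 0.14.

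Amino acid, sterol and iron genes moved in different directions. Slc7a11, the cystine importer that erastin blocks, fell from 36.1 ± 1.04 to 14.1 ± 0.80 CPM, a log2 fold change of −1.36 ± 0.08 (adjusted p 8.94e-09). Other targets of ATF4, the transcription factor of amino acid shortage, fell as well: Asns had −0.96 ± 0.07, Slc7a5 −0.94 ± 0.05, Vldlr −2.41 ± 0.08 and Chac1 −0.84 ± 0.12. Of the ATF4 list 18 of 33 were lower and 1 higher, with a median of −0.328 (adjusted p 2.39e-06, estimated 0.0952). Of 25 cholesterol-synthesis genes 18 were lower and 2 higher (median −0.631, adjusted p 1.41e-07, estimated 0.0105), with Hmgcs1 at −1.31 ± 0.07. Lysosome genes were lower as a list (12 lower and 1 higher of 26, median −0.253, adjusted p 0.00195, estimated 0.222), with Ctsa at −0.99 ± 0.05. Iron genes were higher (12 higher and 4 lower of 21, median 0.234, adjusted p 0.0101, estimated 0.162): the importers Slc11a2 and Tfrc rose by 1.13 ± 0.06 and 0.50 ± 0.07, the ferroxidase Cp by 1.84 ± 0.09, Lcn2, which binds iron carriers, by 5.44 ± 0.37, and the ferritin chain Fth1 by 0.54 ± 0.10. NRF2 targets were split, 13 higher and 6 lower of 24 (median 0.353, adjusted p 0.0424, estimated 0.549), with Akr1b8 at 2.41 ± 0.08, Nqo1 at 0.91 ± 0.07 and Txnrd1 at 0.65 ± 0.05 against Gclc at −0.60 ± 0.05. Bach1, a repressor of NRF2 targets, rose by 1.56 ± 0.09.

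In total 6816 genes changed with erastin under NPPC-Exo, 3362 higher and 3454 lower, and 2005 of them changed at least 2-fold, 1061 higher and 944 lower. With library size alone in place of the trimmed-mean factors the median of all genes moved from 0.0175 to 0.3, the share of higher genes among those changed from 49.3% to 77.8%, and the median of the ATF4 list from −0.328 to −0.045. Of the 13 gene lists called here, 6 had an estimated value under 0.05: those of proliferation, fibroblast and contractile genes, cholesterol, secreted factors, disc matrix and interferon. The calls of the ATF4, endothelial, hypertrophy, apoptosis, lysosome, iron and NRF2 lists did not hold with it.

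**Figure D2:**
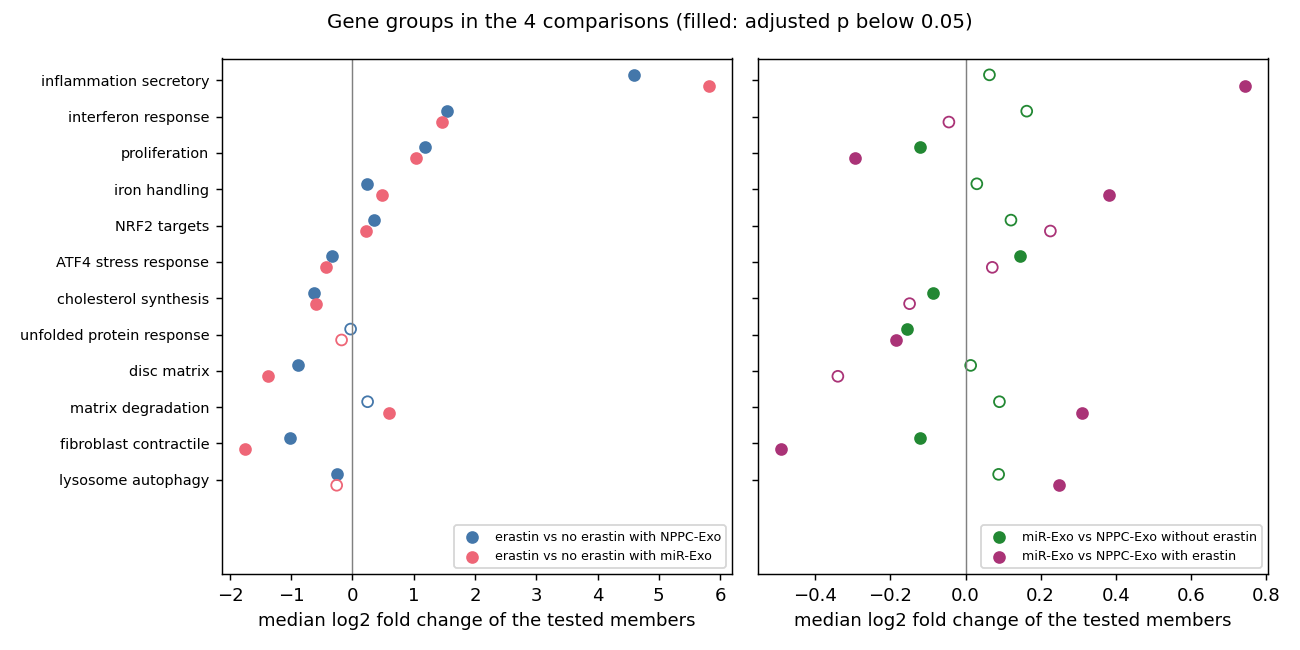
Median log2 fold change of the tested members of 12 gene lists in the 4 comparisons, with genes at 0 counts in a group at their bound, erastin on the left and kind of exosome on the right, each panel with its own scale. Filled circles had an adjusted p under 0.05 in the camera test.

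With miR-Exo, chemokine genes rose with erastin as well. Ccl2, Ccl7 and Cxcl3 rose by 7.07 ± 0.21, 7.11 ± 0.22 and 7.92 ± 0.42, Lcn2 by 7.39 ± 0.38 and Tnfaip3 by 3.28 ± 0.10. Fgr, a kinase of the Src family seen mostly in myeloid cells, had 0 counts in all miR-Exo libraries and 5.00 ± 0.48 CPM with erastin, a rise of at least 99.4-fold. Gbp5 and Cxcl10 rose by 4.44 ± 0.15 and 4.29 ± 0.15. Of the secreted-factor genes 30 of 32 were higher and 1 lower (median 6.01, with bounds 5.82, adjusted p 2.15e-36, estimated 0.0143), and of the interferon genes 19 of 28 were higher and 0 lower (median 1.46, adjusted p 1.58e-07, estimated 0.0479). Proliferation genes were higher in 33 of 34 cases and lower in 0 (median 1.03, adjusted p 7.27e-29, estimated 0.00177), with Kif20a at 1.39 ± 0.04 and Ccnb1 at 1.48 ± 0.06. Apoptosis genes were higher in 11 of 20 cases and lower in 2 (median 0.305, adjusted p 0.000372, estimated 0.199), with Birc3 at 3.68 ± 0.15.

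Transcripts of the cartilage-like matrix fell here as well. Acan fell to 773 ± 20.8 CPM, a log2 fold change of −3.09 ± 0.07, Col2a1 from 1028 ± 191 to 68.0 ± 14.1 CPM, or −3.92 ± 0.22, and Col9a1 had −1.89 ± 0.06. Versican (Vcan), a proteoglycan of loose matrix, instead rose by 2.76 ± 0.08. Its interaction of 0.88 was smaller than this, so its change with erastin was upward under NPPC-Exo as well. Mmp3, Mmp9 and Mmp13 rose by 6.85 ± 0.17, 5.71 ± 0.21 and 6.26 ± 0.29, and Timp3 had −3.69 ± 0.14, in a list of protease inhibitors that was not called (5 higher and 4 lower of 9, median 0.462, adjusted p 0.797). In the disc matrix list 22 of 31 genes were lower and 6 higher (median −1.38, adjusted p 2.58e-08, estimated 0.0315), and in the matrix-degrading list 15 of 24 were higher and 6 lower (median 0.591, adjusted p 0.000351, estimated 0.104). Fibroblast and contractile genes were lower in 28 of 32 cases and higher in 2 (median −1.75, adjusted p 9.99e-41, estimated 0.00163), with Postn at −2.73 ± 0.05, Col12a1 at −2.30 ± 0.05, Acta2 at −2.22 ± 0.06 and Tpm1 at −1.89 ± 0.05. Hypertrophy genes were lower in 10 of 15 cases and higher in 0 (median −1.59, adjusted p 0.00129, estimated 0.0992), with Enpp1 at −1.24 ± 0.05 and Spp1 at −1.07 ± 0.06.

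Esam changed by −6.09 ± 0.15 and Flt1 by −1.90 ± 0.14 in an endothelial list that was lower in 4 of 7 cases and higher in 1 (median −1.54, adjusted p 0.000246, estimated 0.0365). Mrap2 had −7.50 ± 0.17 and Pln, a regulator of the calcium pump of muscle, −6.38 ± 0.15. Of the ATF4 list 24 of 33 genes were lower and 0 higher (median −0.428, adjusted p 2.61e-07, estimated 0.0581), with Vldlr at −2.32 ± 0.08, Chac1 at −1.06 ± 0.12 and Asns at −0.92 ± 0.07. Of the cholesterol list 22 of 25 were lower and 2 higher (median −0.6, adjusted p 2.61e-07, estimated 0.0131), with Idi1 at −1.29 ± 0.06. Iron genes were higher in 14 of 21 cases and lower in 1 (median 0.483, adjusted p 3.54e-06, estimated 0.0274), with Cp at 2.68 ± 0.09, Slc11a2 at 1.67 ± 0.06, Tfrc at 0.97 ± 0.07 and Fth1 at 0.89 ± 0.10. NRF2 targets were higher in 12 of 24 cases and lower in 5 (median 0.217, adjusted p 0.0384, estimated 0.464), with Akr1b8 at 2.16 ± 0.08 and Gstp1 at 1.00 ± 0.08. Lysosome genes were not called here (4 higher and 15 lower of 26, adjusted p 0.0652), with a median of −0.258 close to the −0.253 under NPPC-Exo, and their interaction was not called (adjusted p 0.115). Genes of exosome formation were lower in 13 of 21 cases and higher in 5 (median −0.27, adjusted p 0.0343, estimated 0.183), with the surface tetraspanins Cd81 at −1.42 ± 0.08 and Cd9 at −1.20 ± 0.08. That list was not called under NPPC-Exo (1 higher and 10 lower of 21, adjusted p 0.0731), and its interaction was not called.

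In total 7687 genes changed with erastin under miR-Exo, 3873 higher and 3814 lower, and 2489 changed at least 2-fold, 1128 higher and 1361 lower. The share of higher genes was 50.4%, and 76.4% with library size alone. Of the 14 lists called, 8 had an estimated value under 0.05, iron and endothelial beside the 6 that met it under NPPC-Exo. Of the 798 genes at least 2-fold lower with at least 5 CPM, 38% lay in the lowest 10% of the main component of the spread within groups, described further below.

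**Figure D3:**
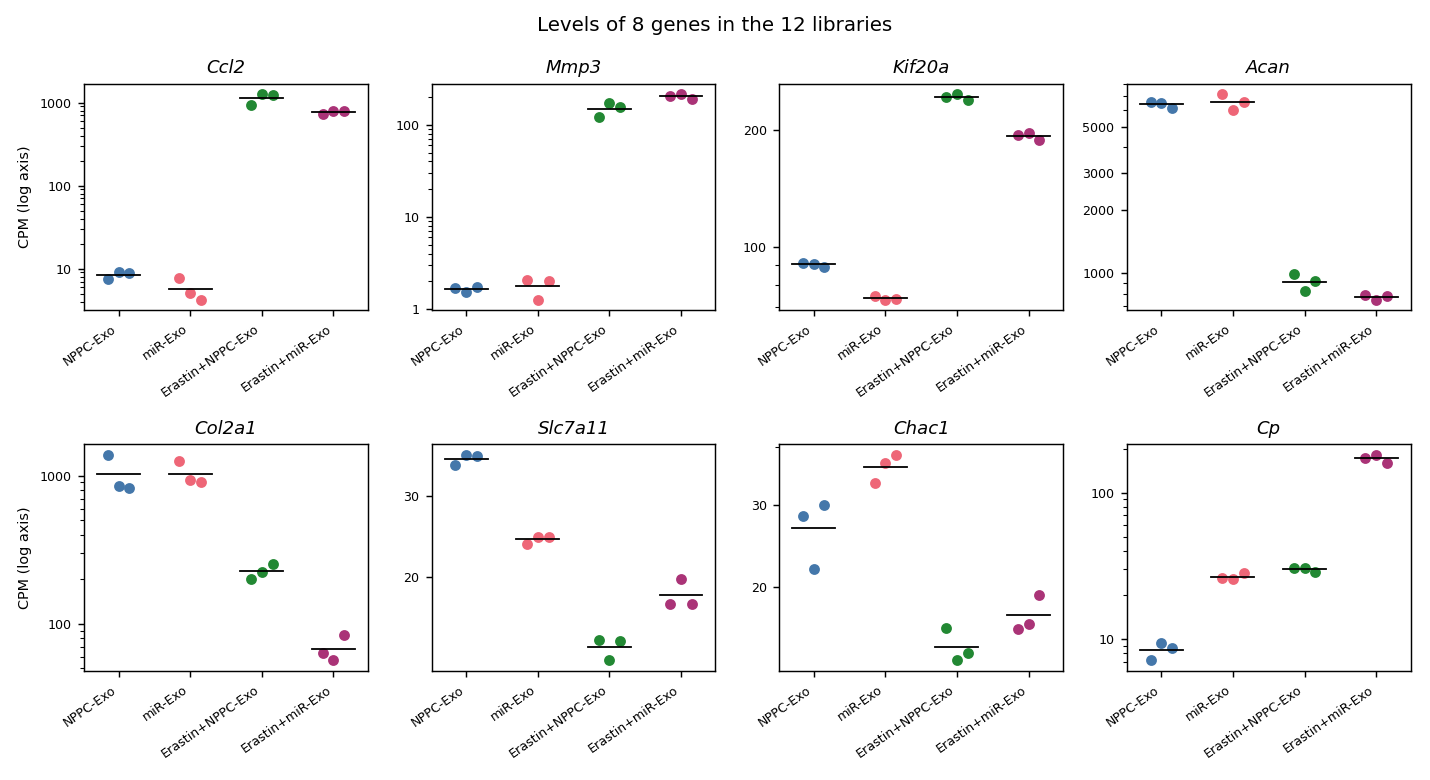
Levels of Ccl2, Mmp3, Kif20a, Acan, Col2a1, Slc7a11, Chac1 and Cp in CPM, on log axes with a scale of their own, for each of the 12 libraries (dots) in the 4 groups; lines are group means.

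Without erastin, fewer genes differed between the kinds of exosome. Pla2g7, an enzyme that breaks down oxidised phospholipids, rose from 3.48 ± 0.48 to 16.0 ± 2.81 CPM, a log2 fold change of 2.20 ± 0.16, and Cpt1b, which brings fatty acids into mitochondria, by 1.76 ± 0.13. Cp, which loads exported iron onto transferrin, rose by 1.67 ± 0.09 and the iron exporter Slc40a1 by 1.09 ± 0.11. The ubiquitin ligase Trim63 rose by 2.46 ± 0.34. The keratin Krt7, Prl8a9 of the prolactin family and the PDZ protein Tax1bp3 fell, with −1.62 ± 0.23, −1.54 ± 0.14 and −1.22 ± 0.07. Bak1, which opens the outer membrane of mitochondria in apoptosis, fell from 79.6 ± 4.61 to 41.4 ± 1.79 CPM, or −0.94 ± 0.06.

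Atf3 and Sesn2 of the ATF4 list rose by 1.45 ± 0.11 and 0.47 ± 0.05, and the amino acid transporters Slc7a5 and Slc7a11 fell, with −0.43 ± 0.05 and −0.58 ± 0.07. The list had 11 of 33 genes higher and 2 lower (median 0.144, adjusted p 0.000549, estimated 0.175). Genes of the unfolded protein response were lower in 8 of 21 cases and higher in 0 (median −0.157, adjusted p 0.000549, estimated 0.126), with the chaperones Pdia6 at −0.55 ± 0.05 and Hyou1 at −0.42 ± 0.05. Heat-shock genes were higher in 4 of 13 cases and lower in 0 (median 0.176, adjusted p 0.00783, estimated 0.175), with Hspb8 at 0.90 ± 0.08. Proliferation genes were lower in 9 of 34 cases and higher in 0 (median −0.122, adjusted p 0.000549, estimated 0.175), with Ccnd1 at −0.47 ± 0.06.

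Itgb1, Cd44 and Thy1, used as markers of disc progenitors, had −0.38 ± 0.04, −0.49 ± 0.05 and −0.32 ± 0.04, in a list lower in 6 of 16 cases and higher in 0 (median −0.19, adjusted p 0.00101, estimated 0.126). Fn1 and Postn had −0.50 ± 0.05 and −0.49 ± 0.05, in a fibroblast list lower in 11 of 32 cases and higher in 2 (median −0.122, adjusted p 0.003, estimated 0.256). Enpp1, which makes the mineralisation blocker pyrophosphate, and Runx2 had −0.68 ± 0.05 and −0.69 ± 0.08, in a hypertrophy list lower in 3 of 15 cases and higher in 0 (median −0.231, adjusted p 0.00391, estimated 0.175). The matrix genes Tnc and Hapln1 had −0.49 ± 0.04 and −0.91 ± 0.10, and the disc matrix list was not called (2 higher and 5 lower of 31, adjusted p 0.32). Cholesterol genes were lower in 6 of 25 cases and higher in 0 (median −0.0862, adjusted p 0.0185, estimated 0.175), with Idi1 at −0.52 ± 0.06 and Hmgcs1 at −0.51 ± 0.07. Glycolysis and hypoxia genes were lower in 7 of 26 cases and higher in 1 (median −0.0765, adjusted p 0.0212, estimated 0.415), with Ca9 at −0.46 ± 0.07 and Bnip3 at −0.53 ± 0.06.

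In total 1669 genes changed between the kinds of exosome without erastin, 649 higher and 1020 lower with miR-Exo, and 213 changed at least 2-fold, 147 higher and 66 lower. With library size alone 68.7% of the changed genes were higher in place of 38.9%. Across genes this comparison went with the component of the spread within groups at a Pearson correlation of −0.314, and 29% of the 31 genes at least 2-fold higher with at least 5 CPM lay in its lowest 10%. None of the 9 lists called here had an estimated value under 0.05, and the lowest was 0.126.

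With erastin present, miR-Exo against NPPC-Exo compares the kinds of exosome in stressed cells. Iron genes were higher with miR-Exo: Cp went from 30.1 ± 1.04 to 172 ± 10.6 CPM, a log2 fold change of 2.52 ± 0.09, Slc40a1 rose by 1.88 ± 0.12, Fth1 by 0.95 ± 0.10 and the zinc and iron importer Slc39a14 by 0.59 ± 0.05. The list was higher in 10 of 21 cases and lower in 1 (median 0.381, adjusted p 4.94e-07, estimated 0.044). Hpx, which binds free haem, rose by 2.84 ± 0.31. Secreted factors were higher in 17 of 32 cases and lower in 4 (median 0.744, adjusted p 0.0102, estimated 0.558), with Lcn2 at 2.20 ± 0.27, Il6 at 1.82 ± 0.13 and Ccl20 at 2.14 ± 0.26 against the IL-33 receptor Il1rl1 at −1.61 ± 0.09.

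The small proteoglycans Dcn and Lum were higher with miR-Exo, by 2.83 ± 0.18 and 1.91 ± 0.08, and Vcan by 0.95 ± 0.07. Col2a1 changed by −1.74 ± 0.20, Col9a2 by −2.17 ± 0.38 and Hapln1, which ties aggrecan to hyaluronan, by −1.61 ± 0.10. The disc matrix list was not called (5 higher and 16 lower of 31, adjusted p 0.0922). The matrix-degrading list was higher in 12 of 24 cases and lower in 2 (median 0.309, adjusted p 0.000523, estimated 0.149), with the plasminogen activator Plat at 1.20 ± 0.10. Fibroblast and contractile genes were lower in 23 of 32 cases and higher in 4 (median −0.491, adjusted p 1.7e-11, estimated 0.044), with Acta2 at −0.91 ± 0.06, Tagln at −0.88 ± 0.07, Tpm1 at −0.75 ± 0.05 and Ccn2 at −0.63 ± 0.04. The laminin chain Lamb3 and Krt7 fell, with −2.78 ± 0.17 and −2.43 ± 0.23. Enpp1 and Spp1 had −1.65 ± 0.05 and −0.69 ± 0.06, in a hypertrophy list lower in 4 of 15 cases and higher in 1 (median −0.468, with bounds −0.193, adjusted p 0.00537, estimated 0.191).

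Proliferation genes were lower in 24 of 34 cases and higher in 3 (median −0.295, adjusted p 3.46e-07, estimated 0.0757), with Ccnd1 at −0.92 ± 0.06 and Cdc20 at −1.08 ± 0.13. Unfolded-protein genes were lower in 13 of 21 cases and higher in 1 (median −0.186, adjusted p 7.39e-05, estimated 0.0575), with Hyou1 at −0.60 ± 0.05 and Pdia6 at −0.57 ± 0.05. Lysosome genes were higher in 14 of 26 cases and lower in 4 (median 0.248, adjusted p 0.00315, estimated 0.232), with the cathepsins Ctsd at 0.61 ± 0.06 and Ctsb at 0.39 ± 0.04. Heat-shock genes were higher in 6 of 13 cases and lower in 1 (median 0.216, adjusted p 0.0165, estimated 0.22), with Hsph1 at 0.63 ± 0.05 and Hspa8 at 0.58 ± 0.06. Transcripts of the mitochondrial genome were higher in 6 of 13 cases and lower in 0 (median 0.175, adjusted p 0.00759, estimated 0.501), with Mt-nd5 at 0.34 ± 0.05. Itgb1 and Thy1 of the progenitor list, lower in 5 of 16 cases and higher in 1 (median −0.262, adjusted p 0.00757, estimated 0.0757), had −0.67 ± 0.04 and −0.57 ± 0.04. The ATF4 list was not called (10 higher and 5 lower of 33, adjusted p 0.219), while its member Atf3 rose by 1.76 ± 0.11.

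In total 4906 genes changed between the kinds of exosome with erastin, 2439 higher and 2467 lower with miR-Exo, and 783 changed at least 2-fold, 371 higher and 412 lower. Of the changed genes 49.7% were higher, and 68.6% with library size alone. Of the 199 genes at least 2-fold lower with at least 5 CPM, 65.3% lay in the lowest 10% of the component of the spread within groups, and across genes this comparison went with the component at a Pearson correlation of 0.418. Of the 11 lists called, those of fibroblast and iron genes had an estimated value under 0.05.

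Whether miR-Exo changed the response to erastin itself was tested as the interaction, in which a positive value is a response more upward with miR-Exo than with NPPC-Exo. Lum stood at 110 ± 9.86 and 101 ± 3.85 CPM without erastin and at 87.7 ± 8.84 and 329 ± 7.25 CPM with it, an interaction of 2.04 ± 0.11. Dcn had 2.43 ± 0.24, Vcan 0.88 ± 0.10 and Hpx 3.46 ± 0.45. Il6 had 2.04 ± 0.19, in a list of secreted factors with 8 of 32 genes higher and 1 lower (median 0.498, adjusted p 0.0361, estimated 0.652). Among iron genes Cp, Slc39a14, Fbxl5, which senses iron, and Slc11a2 had 0.85 ± 0.12, 0.76 ± 0.07, 0.78 ± 0.10 and 0.53 ± 0.09, with 10 of 21 higher and 1 lower (median 0.351, adjusted p 7.02e-05, estimated 0.205). The glycolytic genes Ldha and Pgk1 had 0.58 ± 0.08 and 0.60 ± 0.08, with 8 of 26 higher and 0 lower (median 0.194, adjusted p 0.00138, estimated 0.401). Plat, Adamts1 and Ctsb had 0.88 ± 0.14, 0.56 ± 0.08 and 0.42 ± 0.06, with 7 of 24 matrix-degrading genes higher and 1 lower (median 0.208, adjusted p 0.00128, estimated 0.251). Mitochondrial transcripts were higher in 4 of 13 cases and lower in 0 (median 0.161, adjusted p 0.0175, estimated 0.652).

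The response was more downward with miR-Exo for fibroblast and contractile genes, 12 of 32 lower and 4 higher (median −0.311, adjusted p 1.95e-06, estimated 0.205), with Acta2 and Tpm1 both at −0.64, SE 0.08 and 0.07. Enpp1 had −0.96 ± 0.07 and Il1rl1 −1.03 ± 0.13. Among proliferation genes, 5 of 34 lower and 1 higher (median −0.158, adjusted p 0.0117, estimated 0.547), Cdc20 had −1.16 ± 0.18 and Ccnd1 −0.45 ± 0.09. Among genes of DNA damage and senescence, 5 of 23 lower and 0 higher (median −0.0726, adjusted p 0.0378, estimated 0.223), Plk2 had −0.66 ± 0.08 and Pmaip1 −0.52 ± 0.07. Of the 2006 genes with an interaction 909 had a positive and 1097 a negative value, and 555 reached 2-fold, 152 positive and 403 negative. None of the 8 lists called had an estimated value under 0.05. The self-test, whose simulated libraries shared no component of spread within groups, recovered 71.6% of genes with a true 2-fold interaction.

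Replicates of the same group also differed along a shared direction, and many genes with a negative interaction lay at its end. On it NPPC-Exo replicate 1 (−0.602) and miR-Exo replicate 1 (−0.409) stood apart from the other replicates of their groups (0.202 to 0.366), and Erastin+miR-Exo ran from −0.302 in replicate 3 to 0.28 in replicate 2. The main component of the spread within groups, over 10162 genes with at least 5 CPM, held 30.4% of that spread, and across genes it went with the interaction at a Pearson correlation of 0.6. Of the 270 genes among these at least 2-fold negative in the interaction, 86.3% lay in the lowest 10% of the component, against 7.93% of the other genes. Junb, Map1s, Nfic, Hmga1 and Erf, named here after their values were seen, had interactions of −3.09, −2.50, −2.28, −2.66 and −2.66 and lay in the lowest 1 percent. Of the 75 genes at least 2-fold positive, 22.7% lay in the highest 10%, against 9.91% of the other genes. With each group's component removed, 1176 genes had an interaction in place of 2104 of the same genes, 76 of the 270 negative genes and 66 of the 75 positive genes still passed, and the median of the negative genes went from −1.35 to −0.739. The removal also takes out any effect of treatment that runs along the component, so the loss of a call there does not show its cause. Lum, Dcn, Il6 and Enpp1 then had 1.96, 2.17, 1.93 and −1.02.

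**Figure D4:**
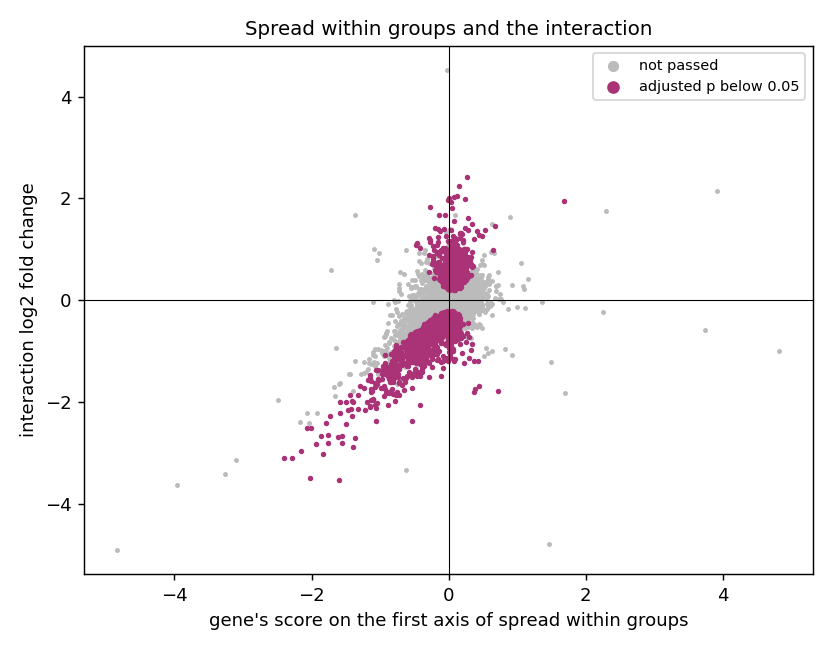
Interaction log2 fold change of each of 10162 genes against its score on the main component of the spread within groups. Coloured dots had an adjusted p under 0.05 for the interaction.

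The responses to erastin under the 2 kinds of exosome had a Pearson correlation of 0.65 across all tested genes and 0.851 across the 8424 genes with a mean FPKM of at least 5. Genes higher in both numbered 2526, where independent lists would share 832, genes lower in both 2423 against 842, and 148 went opposite ways. Of 4389 genes raised by erastin on average, 574 had an interaction, and the rise was larger with miR-Exo for 379 and smaller for 195. Of 4345 genes lowered by erastin, 904 had an interaction, and the fall was larger with miR-Exo for 592 and smaller for 312. The effects of the kind of exosome without and with erastin had a Pearson correlation of 0.197, with 377 genes higher in both (101 by chance), 633 lower in both (161 by chance) and 74 opposite. Cp, Slc40a1, Atf3, Bak1, Krt7 and Enpp1 were among those that kept their direction; Slc7a11, lower with miR-Exo without erastin and higher with it, was not.

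Transcripts widely described as bound by miR-221 would be lower where the miRNA acts on them. Cdkn1b, which encodes the cell-cycle inhibitor p27, changed by −0.64 ± 0.13 with miR-Exo without erastin (adjusted p 0.00868) and by −1.79 ± 0.14 with erastin (adjusted p 1.26e-06), an interaction of −1.15 ± 0.19. Its score lay at percentile 6.32 of the component of the spread within groups, and with that component removed its interaction was −0.74 and still passed. Ets1 and Angptl2 were lower in both comparisons, with −0.36 ± 0.05 and −0.45 ± 0.08 without erastin and −0.55 ± 0.05 and −1.44 ± 0.09 with it, and the interaction of Angptl2 was −0.99 ± 0.12. Timp3 fell with erastin present, by −0.94 ± 0.14. The list of 24 tested targets was not called, with 6 lower and 2 higher without erastin (adjusted p 0.32) and 7 lower and 6 higher with it (adjusted p 0.104). Counted within the list alone, 6 were lower and 3 higher, then 8 lower and 6 higher. Log2 fold changes in the list ran from −0.76 to 1.35 without erastin and from −1.79 to 1.22 with it, and the members named above were among the lower ones. By fry the unadjusted p of this list was 0.0387 without erastin and 0.000721 with it, at medians of −0.0997 and −0.0396. Fry does not set a list against the other genes. With erastin it gave 6.83e-06 for the DNA damage and senescence list and 8.16e-05 for the exosome formation list, neither of them called. The fry values therefore do not single out the targets.

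As a group, genes central to ferroptosis did not shift in 1 direction against the other genes. Of all tested genes 43.55% changed with erastin under NPPC-Exo and 49.12% under miR-Exo. Only 8 of 28 defence genes and 7 of 27 drivers did not pass under NPPC-Exo, and 8 and 8 under miR-Exo. Members of both lists thus changed more often than all genes, some up and some down. The adjusted p of a list tests a shared direction and does not measure this. The list of defence genes had 11 of 28 higher and 9 lower with erastin under NPPC-Exo (adjusted p 0.863) and 12 higher and 8 lower under miR-Exo (adjusted p 0.797), and the list of drivers 11 of 27 higher and 9 lower (adjusted p 0.506) and 12 higher and 7 lower (adjusted p 0.269). Between the kinds of exosome the defence list had adjusted p 0.873 without and 0.336 with erastin, and the driver list 0.32 and 0.993. By fry the unadjusted p with erastin was 0.264 under NPPC-Exo and 0.287 under miR-Exo for defence, and 0.00459 and 0.000148 for drivers. Between the kinds of exosome fry gave 0.954 without and 0.0431 with erastin for defence, and 0.0336 and 0.932 for drivers. Gpx4, which reduces lipid peroxides, stood at 49.1 ± 15.5, 44.7 ± 5.56, 41.0 ± 2.25 and 47.7 ± 11.3 CPM in the order NPPC-Exo, miR-Exo, erastin with NPPC-Exo and erastin with miR-Exo, and passed no test (lowest adjusted p 0.320). Acsl4, which loads polyunsaturated fatty acids for membrane lipids, had −0.04 ± 0.06 with erastin under NPPC-Exo (adjusted p 0.632) and 0.19 ± 0.06 under miR-Exo (adjusted p 0.012, a call lost under 4 other settings). It was higher with miR-Exo under erastin by 0.22 ± 0.06 (adjusted p 0.00832), a call lost without Erastin+NPPC-Exo replicate 2 (0.19), Erastin+NPPC-Exo replicate 3 (0.19) or Erastin+miR-Exo replicate 1 (0.15). With library size alone the value under NPPC-Exo was 0.25 and passed.

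Slc7a11 fell with erastin less under miR-Exo, by −0.40 ± 0.07 (adjusted p 0.000549), than under NPPC-Exo, an interaction of 0.95 ± 0.11 (adjusted p 0.000336), and with erastin present it was higher with miR-Exo by 0.37 ± 0.08. The call of its fall under miR-Exo was lost under 6 other settings, among them library size alone (−0.10). Chac1 was higher with miR-Exo without erastin by 0.44 ± 0.12 (adjusted p 0.0303), a call lost under 4 other settings. Among them were leaving out NPPC-Exo replicate 2 (0.31), miR-Exo replicate 2 (0.43) or miR-Exo replicate 3 (0.40). It did not pass with erastin (0.22 ± 0.12, adjusted p 0.178). Ptgs2, often raised in ferroptosis, rose with erastin by 1.08 ± 0.09 and 1.67 ± 0.09 in the order of NPPC-Exo and miR-Exo, an interaction of 0.58 ± 0.12. It was lower with miR-Exo without erastin (−0.46 ± 0.09, adjusted p 0.00514) and did not pass with it (adjusted p 0.344). Hmox1, which frees iron from haem, changed by −0.34 ± 0.08 and −0.93 ± 0.08, an interaction of −0.59 ± 0.11, and was lower with miR-Exo under erastin by −0.55 ± 0.08. With library size alone its fall under NPPC-Exo was −0.06 and did not pass.

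Tfrc was lower with miR-Exo without erastin (−0.40 ± 0.07, adjusted p 0.00294), did not pass with it (adjusted p 0.525) and had an interaction of 0.47 ± 0.10, which with the component of the spread within groups removed was 0.32 and did not pass. Fth1 was higher with miR-Exo without erastin by 0.60 ± 0.10, and its interaction did not pass (adjusted p 0.131). Col2a1 had an interaction of −1.74 ± 0.28 that was −0.96 and still passed with the component removed; its score lay at percentile 1.72. Acan was lower with miR-Exo under erastin by −0.24 ± 0.07 (adjusted p 0.0179), a call lost under 9 other settings, among them library size alone (−0.13) and leaving out Erastin+NPPC-Exo replicate 1 (−0.20). Mmp3 was higher there by 0.46 ± 0.12 (adjusted p 0.0134), a call lost without Erastin+NPPC-Exo replicate 1 (0.30), Erastin+miR-Exo replicate 1 (0.43) or Erastin+miR-Exo replicate 2 (0.40). Mmp13 was lower with miR-Exo without erastin (−1.03 ± 0.30, adjusted p 0.0454) and had an interaction of 1.37 ± 0.37 (adjusted p 0.0286), and those calls were lost under 17 and 13 other settings. Cdkn1b fell with erastin under miR-Exo by −0.80 ± 0.14 (adjusted p 0.000295). Under NPPC-Exo it had 0.35 ± 0.13 (adjusted p 0.04998), a call at the threshold that was lost under 7 other settings.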

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

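The tests in this part, other than the interaction itself, were chosen after the results were seen. The genes and lists of the last paragraph differed in their response to erastin between the kinds of exosome by the test of the interaction.

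Mir221 had 78.1 times more reads with miR-Exo, and the source of these reads was weighed. Transcription of the cells' own cluster of Mir221 and Mir222 is argued against, since it would carry Mir222 along, and the ratio of Mir222 was 0.853 (0.529 to 1.45 from the spread between libraries). RNA of the precursor or of a vector that the exosomes brought in stays open: Mir221 changed by −0.193 (log2) with erastin in the miR-Exo groups, and no exosome was sequenced alone. RNA made in the treated cells from a transferred construct cannot be told apart from it.

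Genes at least 2-fold negative and at least 2-fold positive in the interaction behaved differently. Of the 270 negative genes with at least 5 CPM, 86.3% lay in the outermost 10% of the component along which replicates of a group also differ. A source of variation that also separates replicates may therefore play a part. The slopes of the groups on the component were −0.0716 for NPPC-Exo, −0.389 for miR-Exo, −0.0863 for Erastin+NPPC-Exo and 0.547 for Erastin+miR-Exo. The miR-Exo groups lay farthest out, so an effect of exosome and erastin together cannot be told apart from such a source. Of the 75 positive genes, 22.7% lay in the matching 10%, against 9.91% of the other genes. With the component removed 66 still passed, which argues against the component as their main cause. What moves the component is not known: Junb, Map1s and Nfic at its end might share a base composition, which could not be tested without sequence, and handling or library preparation is not recorded. A biological effect of miR-Exo on the response to erastin therefore stays open for the positive genes, as a hypothesis, and for the negative genes as well, since 76 of the 270 still passed with the component removed and the removal also takes out any effect of miR-Exo along it.

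Under erastin, genes of secreted factors rose while Chac1 and the ATF4 list were lower, the list without a call at estimated correlation (adjusted p 0.0952 with NPPC-Exo and 0.0581 with miR-Exo). Leukocytes in the cultures are argued against as the main source of Ccl2, which had 1148 CPM with erastin and NPPC-Exo. With erastin the 11 leukocyte genes found together went from 10.2 to 26.3 CPM under NPPC-Exo and from 11.35 to 43.9 CPM under miR-Exo. Cd74 among them went from 1.23 to 10.5 CPM and from 0.428 to 17.4 CPM, in the same order. Secreted factors at low levels are not covered by this comparison. The median of the ATF4 list was −0.328 with trimmed-mean factors and −0.045 with library size alone, which moved the median of all genes as well, so the scaling sets how far the list fell but not its place among other genes. Chac1, usually raised by erastin, had −0.842, and an agent or dose other than the labels give cannot be told apart from a late time point, since 48 h was the only time and no dose is given per library. A biological switch from stress response to cytokine release was not tested.

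Lists with a positive interaction were those of iron (0.351), secreted factors (0.498), matrix degradation (0.208), glycolysis (0.194) and the mitochondrial genome (0.161). Lists with a negative interaction were those of fibroblast and contractile genes (−0.311), proliferation (−0.158) and DNA damage and senescence (−0.0726). With estimated correlation none of these 8 lists had an adjusted p under 0.05, and the lowest was 0.205. The matrix genes Dcn, Lum and Vcan had 2.43, 2.04 and 0.88. Hpx, Cp, Slc39a14, Fbxl5, Slc11a2 and Tfrc, which handle haem and iron, had 3.46, 0.85, 0.76, 0.78, 0.53 and 0.47. The call of Tfrc was lost with the component of the spread within groups removed. Il6, Ptgs2 and Il1rl1 had 2.04, 0.58 and −1.03. The proteases Plat, Adamts1, Ctsb and Mmp13 had 0.88, 0.56, 0.42 and 1.37, where the call of Mmp13 was lost under 13 other settings. The glycolytic genes Ldha and Pgk1 had 0.58 and 0.6, and the transporter Slc7a11 had 0.95. Acta2, Tpm1, Enpp1, Angptl2, Col2a1 and Hmox1 had −0.64, −0.64, −0.96, −0.99, −1.74 and −0.59. Col2a1 lay near the low end of that component. Cdc20, Ccnd1, Cdkn1b, Plk2 and Pmaip1, which act in the cell cycle and in cell death, had −1.16, −0.45, −1.15, −0.66 and −0.52.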

How the results depend on the processing

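Library size alone, halved counts, a minimum of 5 CPM and removal of the component of the spread within groups were tests chosen after the data were seen. Limma-trend with a pseudocount of 1, the planned main test for a table without counts, was also made an alternative then. The other alternatives were chosen before. Across 31 settings, 5840 alternative values of the 237 gene results and 3635 of the 160 list results were computed. Of the gene values 5708 kept their direction and their side of the threshold, 74 no longer passed, 17 newly passed and 34 moved without passing, and of the list values these were 3263, 102, 85 and 185. In the order erastin with NPPC-Exo, erastin with miR-Exo, miR-Exo without erastin, miR-Exo with erastin and interaction, a demand for at least 2-fold change left 2005, 2489, 213, 783 and 555 genes, by its own construction. Array weights raised the counts for miR-Exo without erastin to 2692 and for the interaction to 3716, and removal of the component lowered the interaction to 1176; the cause of the first was not tested. Leaving out single libraries gave 970 to 1854 genes for miR-Exo without erastin, where NPPC-Exo replicate 2 (970) and miR-Exo replicate 2 (1042) moved the count most. For the interaction the range was 1205 to 2419, with 1218 without NPPC-Exo replicate 2, 1272 without miR-Exo replicate 1, 1205 without Erastin+NPPC-Exo replicate 3, 1227 without Erastin+miR-Exo replicate 1 and 1300 without Erastin+miR-Exo replicate 2; fewer libraries were fitted in each. The correlation of the erastin responses was 0.851 among genes with a mean FPKM of at least 5. Acsl4 with erastin under NPPC-Exo turned from −0.04 to 0.25 with library size alone, to 0.23, 0.24 and 0.24 in limma-trend on FPKM with pseudocounts of 1, 0.1 and 0.01, to 0.23 without trend and 0.22 with array weights. Hmox1 there turned from −0.34 to 0.02 (0.0176) with array weights; these settings apply no trimmed-mean factors, and library size alone moved the median of all genes to 0.3. Library size alone gave 50.7% of positive genes in the interaction in place of 45.3%. Deviations of libraries with the same replicate number correlated at −0.0573 to 0.122 across genes. The highest, 0.122, was that of replicate 1 of NPPC-Exo and of miR-Exo, which both stood low on the component (−0.602 and −0.409). A factor shared by those 2 libraries is thus not excluded. A replicate block gave 6720, 7596, 1560, 4847 and 1928 genes in the order above. Calls of gene lists lost most often were those of DNA damage and senescence in the interaction (15 settings), exosome formation with erastin under miR-Exo (11), glycolysis for miR-Exo without erastin (10), NRF2 targets with erastin (10 under miR-Exo and 9 under NPPC-Exo) and secreted factors in the interaction (9). The test of seed sites and its 2 alternatives were not run, as no 3′ UTR sequence was held. Depth limits genes near the floor of 3 counts.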

Other observations

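The tests of gene ontology terms in this part were chosen after the results were seen, and the counts of splits were chosen before. The terms are those of the deposited table, 1865 of them with 15 to 300 tested genes. None in any comparison had an adjusted p under 0.05 with the correlation between genes estimated from the data, given here after the word estimated. Genes of stress fibers, the actin cables that anchor cells to their matrix, were lower with miR-Exo under erastin in 35 of 57 cases and higher in 2 (median −0.516, adjusted p 2.13e-10, estimated 0.51), and had a negative interaction in 22 cases and a positive one in 0 (median −0.431, adjusted p 8.96e-11, estimated 0.901). Among them Actn1, which links actin filaments, had −0.66 ± 0.05 and Fermt2, which activates integrins, −0.56 ± 0.05. Focal adhesion genes were lower in 59 of 128 cases and higher in 14 (median −0.228, adjusted p 1.8e-05, estimated 0.51). The water channel Aqp1, of the sarcolemma term, had −1.98 ± 0.07 in this comparison. That term was not called here (10 higher and 19 lower of 72, adjusted p 0.15). Genes of intraciliary transport, which builds the primary cilium, were higher in 12 of 23 cases and lower in 2 (median 0.318, adjusted p 0.0231, estimated 0.51).

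With erastin under NPPC-Exo, genes of basement membranes were lower in 49 of 80 cases and higher in 15 (median −0.519, adjusted p 6.71e-10, estimated 0.0923), with Fras1 at −5.48 ± 0.16 and Ccdc80 at −2.05 ± 0.04. Genes of the sarcolemma were lower in 36 of 72 cases and higher in 8 (median −0.409, adjusted p 3.38e-06, estimated 0.0923), with Dmd, the dystrophin gene, at −2.97 ± 0.12 and Vcl at −1.60 ± 0.07. Genes that start DNA replication were higher in 12 of 16 cases and lower in 0 (median 0.878, adjusted p 1.07e-09, estimated 0.0923), with the helicase parts Mcm3, Mcm6 and Mcm7 at 1.29 ± 0.06, 1.11 ± 0.05 and 1.20 ± 0.05. Genes of the response to lipopolysaccharide were higher in 58 of 111 cases and lower in 17 (median 0.457, adjusted p 6.76e-09, estimated 0.0923), with Cxcl16 at 5.22 ± 0.14.

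Other splits of the same libraries into groups of the same sizes were counted. Of 10 splits, 1 (the real one) gave as many genes in each comparison of 2 groups: 1669 against a highest other of 2 for miR-Exo without erastin, 4906 against 0 for miR-Exo with erastin, 6816 against 0 for erastin under NPPC-Exo and 7687 against 0 under miR-Exo. The splits are too few for a share under 0.05. For the interaction the kind of exosome was shuffled within each erastin level. Of 100 splits 2, a share of 0.02, gave at least the real 2006, and the highest other gave 2028. That split shuffled only the libraries without erastin, as did 9 splits in all with a median of 1080. The 9 splits that shuffled only the libraries with erastin gave at most 6, with a median of 0, and the 81 that shuffled both gave at most 2. Shuffling only the libraries without erastin left the real difference between the kinds of exosome with erastin, 4906 genes, inside the interaction. Other shuffling moved that difference into the spread within groups. The share of 0.02 therefore cannot test the interaction apart from the effect of the kind of exosome.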
